A study of Mus musculus with 22 samples.

How the data were processed

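RNA sequencing was done on 22 samples of mouse cells, per the labels with TruSeq libraries and, for 20 of them, from embryonic fibroblasts carrying the OG2 reporter transgene that were sampled after 2 days of transfection and a number of further days. The labels do not say how the transfection was done or with what vector. The 20 samples are 6 arms: OvSvK on days 0 to 4, OSK on days 0, 1, 3, 5 and 7, GFP on days 1, 3, 5 and 7, and OSK without bFGF, without vitamin C or without GSK3 inhibitors on days 3 and 7. The other 2 samples are mouse embryonic stem cells (mESC) and mouse embryonic fibroblasts (MEF). Every arm and day is 1 library, so no group has a replicate.

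Per the submitters' processing notes, expression was estimated with RSEM 1.2.4 on the mm10 build for the 20 libraries and with RSEM 1.1.21 on mm9 for mESC and MEF. Aligner settings, library strandedness, read length and sequencing runs are not given in the sources used here. The deposited table of each of the 20 libraries gives 24130 genes with expected counts, which RSEM makes by sharing ambiguous reads among genes, and with TPM, transcript abundances scaled to a fixed sum, named so per the file headers. The deposited table of the whole series holds 12897 genes in 22 columns under a name that calls them CPM. Its values are whole numbers that share 1 median (374) and 1 maximum (58542) in all 22 columns, which is the form of quantile-normalized values. They were therefore read as a score made by the authors, not as counts or CPM, and were used only for similarity to mESC and MEF and as an alternative. Symbols came from the series table for 12897 identifiers and from the reference annotation for 10788, and 445 identifiers stayed without a symbol. Coordinates are those of the mm10 build.

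Expected counts were rounded and analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 for tables and plots. Library sizes were scaled by TMM, genes with low counts were removed by filterByExpr with the arm as group, and quasi-likelihood models with robust dispersion were tested. P-values were adjusted by Benjamini-Hochberg over all genes of a test, with a threshold of 0.05. With 1 library per arm and day, the error in these tests is how differences between arms vary from day to day, or how values depart from a straight line over days. It is not the spread between replicates. OSK was compared with GFP on days 1, 3, 5 and 7 with day as a block (8 libraries, 12680 genes, 3 residual degrees of freedom). OvSvK was compared with OSK on days 0, 1 and 3 in the same way (6 libraries, 12910 genes, 2 residual degrees of freedom). Changes per day in OvSvK, OSK and GFP, and their differences, came from 1 model of 14 libraries with a line per arm (13848 genes, 8 residual degrees of freedom). Omissions were compared with OSK on days 3 and 7 in 1 model with day as a block (8 libraries, 14191 genes, 3 residual degrees of freedom). The biological coefficients of variation of these models were 0.32, 0.36, 0.35 and 0.20. The 16 pairs of libraries compared on single days, and mESC with MEF, have no test and are values only. Such pairs used a prior count of 2, and a gene counted as higher or lower at a 2-fold difference with at least 5 CPM (counts scaled by library total times TMM factor) in 1 of both libraries.

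The 26 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule took Pou5f1, Sox2 and Klf4 in each comparison, then the 10 largest fitted changes in each direction among genes past the threshold with a mean of at least 5 CPM, up to 6 members per list with the smallest p, and for single days the 5 largest ratios in each direction with at least 10 CPM in 1 library. Col1a1, Ifit1, T, Xist, Myh2 and the Y-linked genes, and the days shown for other named genes, were chosen after their values were seen. Lists with at least 3 tested members were tested with camera, with a preset correlation of 0.01 and with a correlation estimated from the residuals. The p-values given for lists are those with the estimated correlation, adjusted over the lists. Those with the preset correlation are not given. In the matched-day and omission models the estimate rests on only 2 or 3 residual degrees of freedom. A list that did not pass there is therefore not shown to be unchanged. On single days a list's median ratio was placed among 10000 random lists of genes with similar expression, ranked by the higher CPM of both libraries. Random genes were drawn within 150 ranks on either side of each member, with a fixed seed. Intervals are 95% Poisson intervals of counts or 95% Wilson intervals of shares, and a count of 0 was given an upper limit of 3 counts per library. Intervals and limits cover counting error only. Library totals ran from 7872277 to 20720718 counts. After TMM scaling the limit of 3 counts lay between 0.147 and 0.399 CPM.

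The models were tested on simulated data made from the same libraries, with 200 changed genes per contrast. The simulated counts held no day effects, library sets or GC trend, and genes varied independently. The shares and false calls below therefore hold for such data and may differ in the real libraries. Of simulated changes of 2 (log2), 80.6% were recovered for OSK against GFP, 73.5% for OvSvK against OSK and 83% to 87% for the omissions against OSK. Of simulated changes of 1 these shares were 11.2%, 8.2% and 31.6% to 37.4%. False calls among unchanged genes were 10 for OSK against GFP, 8 for OvSvK against OSK, 10 without bFGF, 22 without vitamin C and 10 without GSK3 inhibitors, in each case more than 0.05 of all calls. For changes per day of 0.5 (log2) the recovered shares were 71% in OSK, 40.8% in GFP, 2% for OSK against GFP, and 0% in OvSvK and for OvSvK against OSK.

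Fixed alternatives were the size factors of DESeq2 1.42.0 (RLE), no low-count filter, DESeq2 in place of edgeR, limma-trend on log2(TPM + 1), 1 model over all 20 libraries, the order of sampling points in place of days, other prior counts and floors, and leaving out each day or library. For the omissions only libraries of the other 2 omissions were left out, not those of OSK or of the omission itself. Alternatives chosen after seeing the data were removal of a trend with GC content, limma-trend on the series table, protein-coding genes only, leaving out OSK day 0 with GFP day 1, and comparing each omission with the other 2 omissions. The last was added because libraries fell into 2 sets by the share of a pseudogene in their counts, as the report describes. The GC trend was a smooth curve per library in the models, and was interpolated between medians of narrow groups of genes elsewhere. The 5 equal groups of genes by GC content served only to describe the libraries. Left out of all tests were mESC and MEF, for which only the series table gives values. The values of 1 gene that the rule named are not reported here.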

Results

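Expression was measured in 20 libraries of fibroblasts taken on successive days after 2 days of transfection, and in mESC and MEF as end points. OSK stands for Oct4, Sox2 and Klf4. OvSvK stands for the same factors with Oct4 and Sox2 each fused to VP16, a viral transcription-activating domain. GFP is the arm without the factors, taken as the control. The series describes OvSvK as a course of 4 days and OSK as a course of 7 days. Totals lay between 8807743 and 17783282 expected counts in OvSvK, 9226523 and 20720718 in OSK, 8568740 and 12623507 in GFP, and 7872277 and 18732098 in the omissions. No arm and day had a replicate (n = 1 throughout), so every error below describes variation of a difference between days or departure from a line over days.

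The libraries fell into 2 sets that the arms and days only partly explain. The processed pseudogene Rpsa-ps10 held 3.32% to 7.78% of the counts shared by it and its parent gene Rpsa in OSK days 1 to 7 and GFP (8 libraries, set 1). It held 0.124% to 0.476% in OvSvK, OSK day 0 and all omissions (12 libraries, set 2). The predicted gene AC136976.1 had 1 to 1582 counts in each library of set 1 and 0 counts in every library of set 2. OSK against GFP on matched days therefore lay within set 1. OvSvK, OSK day 0 and the omissions lay within set 2. OvSvK against OSK on days 1 and 3, and each omission against OSK, crossed the sets, so that arm and set cannot be told apart there. Changes per day in OSK also crossed them, between day 0 and the later days. OSK day 0 also stood apart from the other 19 libraries. Its genes in the lowest and highest of 5 groups by GC content deviated by -1.67 and 1.19 (log2), against -0.94 to 0.61 and -0.28 to 0.40 elsewhere. Its rank correlation with the series table was 0.914, against at least 0.959, and its TMM factor 0.674, against at least 0.853. Slopes in OSK and the comparison of OvSvK with OSK on day 0 rest in part on this library. GFP day 1 came next, at -0.94 and 0.40, with a rank correlation of 0.959. The deviation of the lowest GC group also rose with day, from -0.34 on day 1 to 0.61 on day 7 of OSK. In GFP it rose from -0.94 to 0.34 over the same days. Changes per day in OSK and GFP therefore ran together with a GC trend. In OvSvK it was -0.17 on day 0, 0.5 on day 1 and 0.28 on day 4.

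The 3 factors were transcribed at high levels in both factor arms, in different proportions. Pou5f1 (Oct4, ENSMUSG00000024406, mm10 chromosome 17, 35506018 to 35510772) stood at 715 to 1030 CPM in OvSvK and at 59 to 267 CPM in OSK. Its counts in GFP were 0 on days 1, 3 and 5, which allows up to 0.377, 0.354 and 0.369 CPM, and 1 on day 7. Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) stood at 937 CPM (95% interval 921 to 954) on day 0 of OSK, the library that stood apart. It stood at 408, 176 and 281 CPM on days 1, 3 and 5 and at 226 CPM (219 to 233) on day 7. Its slope was -0.26 log2 per day (SE 0.08, adjusted p = 0.0262), though day 7 lay above day 3. In OvSvK Sox2 lay at 115 to 192 CPM. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) lay at 365 to 1200 CPM in OSK, at 365 to 717 CPM in OvSvK and at 28.1 to 73.5 CPM in GFP. The counts do not separate transcripts of introduced factors from those of the native genes.

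OSK against GFP asks what the factors did beyond transfection. The threonine dehydrogenase gene Tdh, active in mESC, rose from 9.35 CPM on day 1 to 346 CPM on day 7 of OSK, at least 1320-fold above GFP on day 7, where its count was 0. L1td1, an RNA-binding protein of pluripotent cells, reached 511 CPM. The adhesion gene Cdh1 (E-cadherin, ENSMUSG00000000303, chromosome 8, 106603351 to 106670246) went from 6.64 to 322 CPM, against 0 to 2 counts in each GFP library, and its fitted difference was 9.59 on the log2 scale (SE 0.89, adjusted p = 0.00241). Collagen gene Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) went the other way, from 3460 CPM on day 1 to 316 CPM on day 7 of OSK, while GFP stayed between 6230 and 9890 CPM.

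Across the 4 matched days, 2126 of 12680 genes were higher and 1769 lower in OSK. The differences of Pou5f1 (log2 11.88, SE 0.36, adjusted p = 0.00041), Sox2 (9.34, SE 0.35) and Klf4 (3.12, SE 0.40, adjusted p = 0.00508) passed, as did that of Myc (1.26, SE 0.21). Of 8 tested early pluripotency genes, 6 were higher, among them Alpl, an alkaline phosphatase (9.96, SE 1.03) and Upp1 (4.61), and Fut4 alone was lower (-4.39, SE 0.38). The counts were the same adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Of 9 tested late pluripotency genes, 3 were higher, with Tfcp2l1 at 7.41 (SE 1.17), or 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Among 12 epithelial genes 4 were higher, such as the desmosome gene Dsp (3.00) and the splicing factor gene Esrp2 (2.24), and the keratin gene Krt18 was lower (-2.95, SE 0.20). There were 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.673 with an estimated correlation).

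Of 32 fibroblast and mesenchymal genes, 20 were lower in OSK and only Cdh2 (N-cadherin, 1.22, SE 0.16) was higher. Among those lower were the mesenchymal transcription factor genes Twist2 (-3.95, SE 0.35, adjusted p = 0.00214) and Snai1 (-3.16, SE 0.30), the growth factor receptor gene Pdgfrb (-3.01) and the collagen cross-linking gene Loxl1 (-4.04). Adjusted over the list alone, 27 were lower and 1 higher (adjusted p = 0.59 with an estimated correlation). TGF-beta targets had 8 of 16 members lower, including Postn (-4.38) and Tgfb3 (-2.32), and Ctgf higher (1.88), or 10 lower and 2 higher adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). Other matrix genes lower in OSK were Dpt (-6.52), Mfap4 (-5.98) and Ltbp2 (-6.10, SE 1.47, adjusted p = 0.0303). The calls of Mfap4 and Ltbp2 were lost without day 3, 5 or 7. The receptor gene Il1rl1 fell to 1.39 CPM on day 7 against 234 CPM in GFP.

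Among 23 DNA methylation and chromatin enzymes, 13 were higher in OSK than in GFP and none lower, including the dioxygenase gene Tet2 (2.16, SE 0.15, adjusted p = 0.00104) and the polycomb cofactor gene Jarid2 (2.13). These were 15 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Cell cycle genes had 7 of 24 higher, such as Mki67 (2.55, SE 0.57, adjusted p = 0.0242) and Rrm2 (2.07), or 8 adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). With DESeq2 22 of the 24 passed, and with the GC trend removed 3. Of 15 p53 and senescence genes 6 were lower, including the cell cycle inhibitor genes Cdkn2b (-2.78, SE 0.35) and Cdkn2a (-1.85, SE 0.21), with 6 also adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). The imprinted genes split, with 3 higher, such as Peg10 (3.05), and 6 lower, such as H19 (-4.52, SE 0.47) and Cdkn1c (-3.60). Adjusted over the list alone they were 3 and 8 (adjusted p = 0.673 with an estimated correlation). FGF/ERK targets split as well, with 5 of 20 higher, led by Spry4 (2.72, SE 0.14), and 4 lower. Adjusted over the list alone they were 6 and 4, and the median of 0.23 and mean of -0.05 differed in sign (adjusted p = 0.832 with an estimated correlation). The count of 3895 genes moved to 933 without day 5, 1181 without day 3 and 6012 without day 1, and 1 model over all 20 libraries called 5856.

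**Figure D1:**
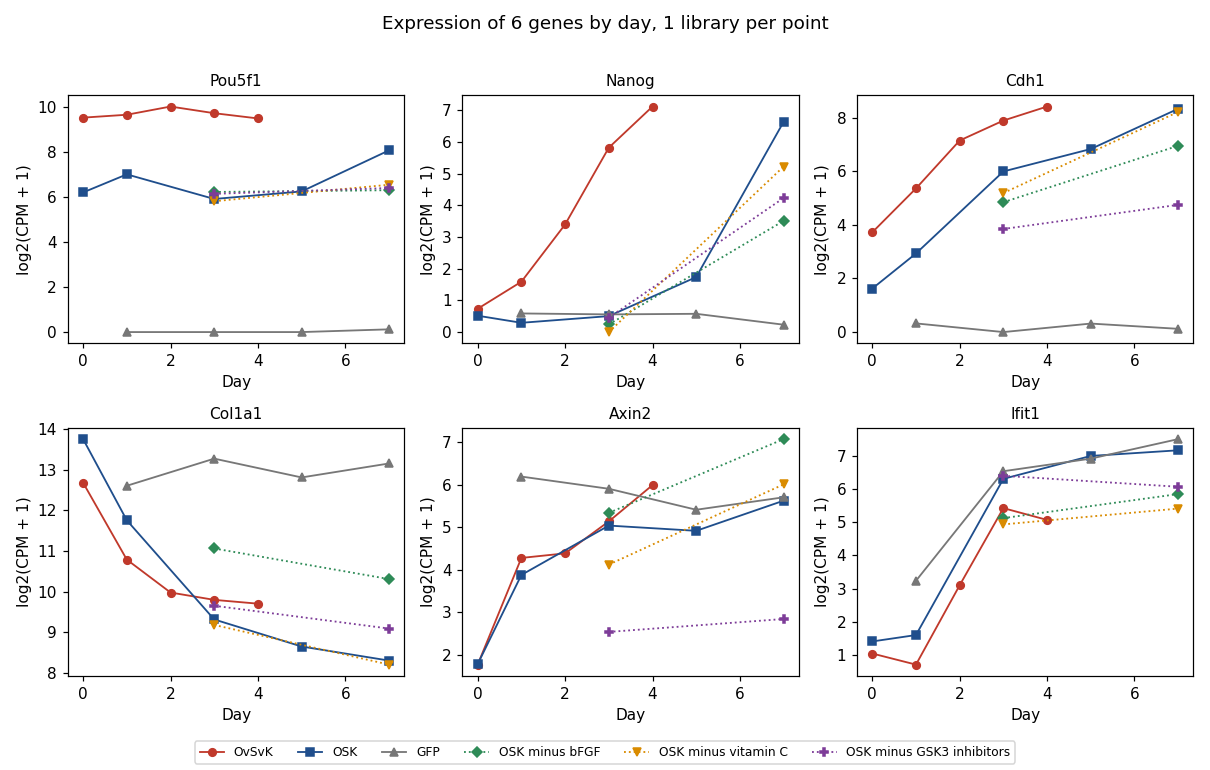
Expression of Pou5f1, Nanog, Cdh1, Col1a1, Axin2 and Ifit1 as log2(CPM + 1) against day, 1 library per point, with a line per arm. Nanog reached 138 CPM on day 4 of OvSvK and 98.5 CPM on day 7 of OSK, and stayed at or under 0.503 CPM in GFP.

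Changes over days show the order of events within each arm. In OSK, Lin28a, an RNA-binding protein of stem cells, had the largest positive slope among the named genes (2.78 log2 per day, SE 0.29, adjusted p = 0.000586), though its counts were 0 until day 5 and 3.87 CPM on day 7. Late pluripotency genes rose mainly at the end. Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633) went from 2.33 CPM on day 5 to 98.5 CPM on day 7, and Dppa5a from 0.111 to 91.9 CPM. Cdh1 was already at 62.8 CPM on day 3. Among early pluripotency genes, 13 of 15 rose per day and 1 fell, with Tdgf1 at 1.87 (SE 0.18), Sall4 at 1.43 (SE 0.24) and Epcam at 1.33 (SE 0.20), and the same counts adjusted over the list alone (adjusted p = 0.0512 with an estimated correlation). Late genes had 10 of 16 rising, such as Nanog (1.30, SE 0.17), Esrrb (1.34, SE 0.20) and Zfp42 (1.27), with 10 also adjusted over the list alone (adjusted p = 0.14 with an estimated correlation).

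Epithelial genes rose in OSK too, 17 of 22, with Esrp1 at 1.98 per day and the desmosome gene Dsg2 at 1.06 (SE 0.08, adjusted p = 0.000123), and 1 fell, again with the same counts adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). The smooth muscle genes Cnn1 (-3.47 per day, SE 0.34) and Tagln (-1.50, SE 0.27) fell. Fibroblast genes had 23 of 32 falling and 2 rising, such as Col6a3 at -0.42 (SE 0.04), or 24 falling adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). TGF-beta targets had 11 of 16 falling, or 12 adjusted over the list alone (adjusted p = 0.345 with an estimated correlation). Stress response genes had 11 of 13 falling, with 11 also adjusted over the list alone (adjusted p = 0.512 with an estimated correlation). Their level was 6.77 on day 0, 4.85 on day 1 and 4.30 to 4.47 from day 3 on. With the GC trend removed 6 fell, and none once OSK day 0 and GFP day 1 were left out. Interferon response genes had 12 of 20 rising, or 14 adjusted over the list alone (adjusted p = 0.506 with an estimated correlation), and only 1 rose once OSK day 0 and GFP day 1 were left out. In all, 2977 genes rose and 3321 fell along OSK, and 2908 passed without OSK day 0, the only OSK library of set 2. On log2(TPM + 1) 3992 rose and 1327 fell. With the GC trend removed 4795 passed, of which 3489 had passed before in the same direction and 64 in the opposite direction.

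In OvSvK 622 genes rose and 804 fell over 4 days. On log2(TPM + 1) 1284 rose and 400 fell, and without OvSvK day 0 141 rose and 48 fell. Tdgf1, a Nodal co-receptor gene, rose by 4.22 per day (SE 0.37, adjusted p = 0.000933), Esrrb by 2.89 (SE 0.40), Lin28a by 2.73 (SE 0.23) and Nanog by 2.05 (SE 0.31). Epithelial genes had 16 of 22 rising, with 16 also adjusted over the list alone (adjusted p = 0.00407 with an estimated correlation), among them Esrp1 (2.60, SE 0.19) and Cldn4 (2.34). Late pluripotency genes had 10 of 16 rising, or 11 adjusted over the list alone (adjusted p = 0.00491 with an estimated correlation), and early genes 9 of 15, or 10 (adjusted p = 0.00839 with an estimated correlation). Neural genes had 4 of 11 rising, including Gfap (1.39) and Sox1 (1.72), and Ncam1 falling (-0.68), or 5 and 1 adjusted over the list alone (adjusted p = 0.0492 with an estimated correlation). These 4 lists were the only ones of any comparison that passed with an estimated correlation.

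Some antiviral and interferon-inducible genes also rose in OvSvK, though the interferon response list did not pass with an estimated correlation. The GTPase genes Iigp1 (3.28 per day, SE 0.64) and Tgtp2 (3.22, SE 0.46), Ifit3 (1.91, SE 0.41) and the chemokine gene Cxcl10 (2.15, SE 0.47) rose. Of the 20 interferon response genes 12 rose, or all 20 adjusted over the list alone (adjusted p = 0.131 with an estimated correlation). The list's mean log2(CPM + 1) was 2.13 on day 1 and 5.55 on day 3 of OvSvK, 2.79 and 5.63 in OSK, and 3.39 and 4.89 in GFP. Among fibroblast genes 15 of 32 fell, led by the collagen cross-linking gene Lox (-1.40, SE 0.13, adjusted p = 0.000567), or 22 adjusted over the list alone (adjusted p = 0.0669 with an estimated correlation). Of 16 TGF-beta targets 9 fell, such as Thbs1 (-1.61), or 13 adjusted over the list alone (adjusted p = 0.0756 with an estimated correlation). The methyltransferase gene Dnmt3b (1.54, SE 0.17) and Tet1 (1.27, SE 0.16) rose. The 1426 calls became 189 without OvSvK day 0, 420 without day 4 and 595 without day 3, and 2651 without OSK day 0. Iigp1, Sall4, Tgtp1, Gbp3 and Tagln were among 12 named genes whose calls ended without OvSvK day 0.

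In GFP 287 genes rose and 378 fell. Proliferation genes fell, 16 of 24 cell cycle genes, such as the kinase gene Plk1 (-0.78 per day, SE 0.08, adjusted p = 0.000995) and Kif2c (-0.81, SE 0.07), or 17 adjusted over the list alone (adjusted p = 0.277 with an estimated correlation). The list's level went from 6.76 on day 1 to 3.93 on day 7 of GFP and stayed between 6.35 and 7.09 in OSK. The collagenase gene Mmp13 rose by 0.97 (SE 0.14), from 7.29 to 432 CPM. Without GFP day 1 or GFP day 7 no gene passed (edgeR), against 665 with all libraries and 2224 by DESeq2. The count was 142 without GFP day 5, 206 to 359 without OvSvK day 2, 3 or 4 or OSK day 5, 1102 without GFP day 3 or OSK day 7, and 2646 without OSK day 0.

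The slopes of OSK and GFP differed in 862 genes, 394 with the higher slope in OSK and 468 with the lower. Cell cycle genes had 16 of 24 with a higher slope, such as Ccnb1 (0.86, SE 0.11, adjusted p = 0.00283), or 21 adjusted over the list alone, fibroblast genes 13 of 32 with a lower slope, such as Col6a3 (-0.70, SE 0.07), or 22, and epithelial genes 8 of 22 with a higher slope, such as Grhl2 (3.15, SE 0.35), or 9. For each of these 3 lists adjusted p = 0.081 with an estimated correlation. Nanog (1.49, SE 0.39, adjusted p = 0.0438) and the matrix gene Ltbp2 (-1.65, SE 0.24) also differed. With DESeq2 1796 genes differed. Without GFP day 1 none passed (edgeR), without GFP day 7 12 did, and without OSK day 7 530, OvSvK day 3 495, OSK day 5 544, OvSvK day 2 562 or GFP day 5 400. Of the 20 named genes, all lost their calls without GFP day 1 or GFP day 7. That of Nanog also ended without GFP day 3 or 5, OSK day 1 or 7, or any 1 library of OvSvK.

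**Figure D2:**
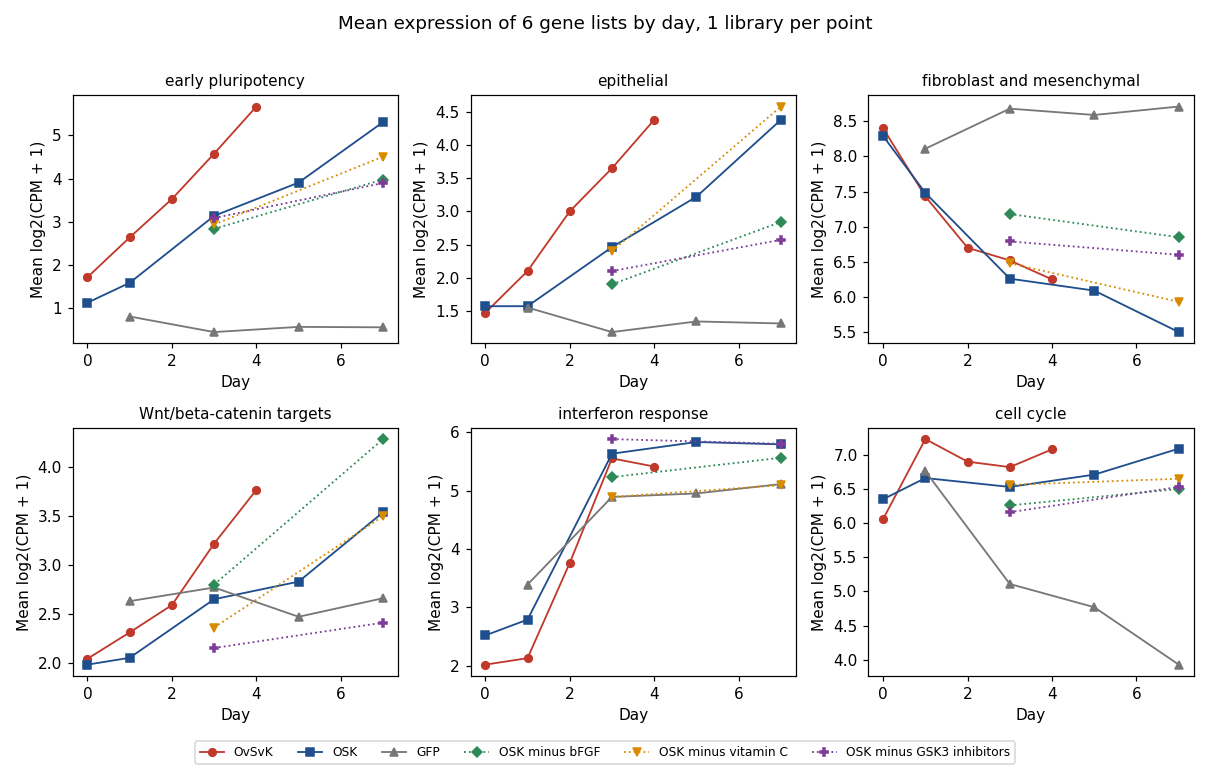
Mean log2(CPM + 1) of 6 gene lists against day, 1 library per point, with a line per arm. Early pluripotency genes reached 5.67 on day 4 of OvSvK and 5.31 on day 7 of OSK, and Wnt/beta-catenin targets on day 7 lay at 4.29 without bFGF, 3.54 in OSK and 2.41 without GSK3 inhibitors.

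OvSvK against OSK compares the factors with and without VP16 fusions. Another stock of cells is not excluded as a source of differences, since Xist stood at 163 CPM in OvSvK and 3.72 CPM in OSK already on day 0. On days 1 and 3 the early and late pluripotency lists had higher medians in OvSvK. On day 3 Nanog stood at 55.5 CPM in OvSvK and 0.418 CPM in OSK, Cdh1 at 237 and 62.8 CPM, and Lin28a at 19.7 CPM against 0 counts, at least 62.9-fold higher. The ratio of the late pluripotency list had a median of 2.13 on the log2 scale, and those of the early, epithelial and neural lists were 1.91, 1.81 and 1.69, each above all 10000 random lists of similar expression. Lists of other lineages went both ways. Primitive streak and mesoderm had a median of 4.11 (percentile 99.99, 4 members), myogenic cells 2.58 (99.76), trophoblast 2.02 (99.88) and endothelial cells 1.99 (99.92, with 1 of 6 counted as 2-fold higher). Endoderm had -0.99 (percentile 0.87, 4 members) and macrophages -1.52 (percentile 0.16, 3 members). Rfx4, a transcription factor gene of neural tissue, stood at 127 against 0.732 CPM and the neuropeptide gene Pdyn at 49.5 against 0.209 CPM. Lower in OvSvK were Tyrp1, a melanosome enzyme (0.139 against 17.7 CPM), and Arhgap36 (0.556 against 39.6 CPM).

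On day 0, where both libraries belong to set 2, 2695 genes were at least 2-fold higher and 2374 lower in OvSvK. Early pluripotency genes had a median of 1.66 (percentile 99.7), late genes 0.42 (percentile 68.46) and interferon response genes -1.07 (percentile 0.04). Macrophage genes had a median of -1.75 (percentile 0, with 8 of 11 at least 2-fold lower) and glycolysis genes -1.08 (percentile 0.94). With the GC trend removed the medians were 1.52 for early, 1.23 for late, -0.91 for interferon response, -0.92 for macrophage and -0.37 for glycolysis genes. Slc22a3, at 13.3 CPM against 0 counts, was at least 61.9-fold higher, and Fam220a was at least 105-fold lower. On day 1 the early and late medians were 2.01 and 2.42, those of the neural and trophoblast lists 1.63 and 1.53, and Insm1, a neuroendocrine transcription factor gene, was at least 129-fold higher. With the GC trend removed, the number of genes at least 2-fold apart on day 0 went from 5069 to 2046.

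No gene passed for OvSvK against OSK over days 0, 1 and 3 with edgeR, where 2991 genes had an unadjusted p under 0.05, while DESeq2 called 1787, limma-trend on log2(TPM + 1) called 0, and on series scores limma-trend called 1. The nearest were Pou5f1 (log2 3.28, SE 0.35), Cdh1 (2.35, SE 0.35), Epcam (3.16, SE 0.51), L1td1 (2.89, SE 0.46), Peg10 (3.28, SE 0.48) and Nr0b1, a nuclear receptor gene of stem cells (4.20, SE 0.64), each with adjusted p = 0.0538. Alpl had a negative difference (-2.58, SE 0.52, adjusted p = 0.059), Sox2 -1.41 (SE 0.53) and Klf4 -0.16 (SE 0.41). No list member passed over all genes. Adjusted over the list alone, 5 of the early pluripotency genes were higher and 1 lower, and 4 of the late and 4 of the neural genes were higher (adjusted p = 0.55 with an estimated correlation for each). Chromatin enzymes had 6 higher in that way, led by Tet1 (2.46, SE 0.46, adjusted p = 0.0546 over all genes), again with adjusted p = 0.55 with an estimated correlation. The count went from 0 to 17 without day 1, 1263 without day 0 and 1748 without day 3. It was 233 with the GC trend removed, and 1187 with that and without day 0.

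The slopes of OvSvK and OSK differed in no gene with edgeR (1681 with an unadjusted p under 0.05), in 405 with DESeq2, and with limma-trend in 56 on log2(TPM + 1) and 47 on series scores. Fgf9 came nearest (-1.35, SE 0.20, adjusted p = 0.0522), then Cldn4 (1.85, SE 0.32), Lox (-0.83, SE 0.14) and Dnmt3b (1.09, SE 0.19), each with adjusted p = 0.0682. Nanog had 0.76 (SE 0.37, adjusted p = 0.459). Adjusted over the list alone, 5 epithelial genes had the higher slope in OvSvK (adjusted p = 0.265 with an estimated correlation). Without OSK day 7 14 genes passed, without OvSvK day 4 3, and without OSK day 0 1.

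The last day of each course gave similar levels of some stem cell genes and different levels of others. Nanog stood at 138 CPM on day 4 of OvSvK and 98.5 CPM on day 7 of OSK, Sall4 at 131 and 138 CPM, Dppa5a at 88.2 and 91.9 CPM, and Cdh1 at 341 and 322 CPM. Lin28a stood at 89.6 against 3.87 CPM, Utf1 at 24.6 against 3.38 CPM, Tet1 at 116 against 42.8 CPM and Pou5f1 at 715 against 267 CPM. The late list had a median log2 ratio of 0.86 (percentile 99.99), the early list 0.07 (88.01) and the epithelial list -0.05 (66.2). Fibroblast genes were higher in OvSvK, with a median of 0.68 (percentile 100), Col1a1 at 835 against 316 CPM. The mesoderm gene T stood at 10.1 against 0.181 CPM. In all, 1228 genes were at least 2-fold higher on day 4 of OvSvK and 1146 lower, with Batf2 at least 67.3-fold higher and the albumin gene Alb at 0.165 against 41.8 CPM. These libraries belong to different sets and have no test.

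The omissions ask what each supplement contributed to OSK. Each was compared with OSK, across the sets, and then with the other 2 omissions, within set 2. The second comparison asks how an omission differs from the other omissions, not from OSK, so an effect shared by all omissions is lost there. The factors themselves differed from OSK. On day 3 Sox2 stood at 443 CPM without bFGF, 434 without vitamin C and 581 without GSK3 inhibitors, against 176 CPM in OSK, and the list of reprogramming factors, which includes Myc, had medians of 0.92, 0.78 and 1.07. On day 7 Pou5f1 stood at 77.6, 92 and 83.1 CPM against 267 CPM in OSK. Without GSK3 inhibitors, some targets of Wnt/beta-catenin, the pathway that GSK3 inhibition activates, were lower. Axin2, a direct target (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), stood at 4.8 and 6.16 CPM on days 3 and 7 against 31.9 and 48.4 CPM in OSK (log2 -2.85, SE 0.40, adjusted p = 0.00268). The difference was -3.17 (SE 0.38, adjusted p = 0.00264) against the other 2 omissions. Cdx1 had 0 counts on both days, against 7.73 CPM on day 7 of OSK, and Sp8 was at least 47.9-fold lower on day 7. Of 19 list members 11 were lower and 2 higher, such as Cyp26a1, a retinoic acid hydroxylase gene (3.01, SE 0.54, and 4.95 within set 2), or 12 lower and 3 higher adjusted over the list alone (adjusted p = 0.576 with an estimated correlation). Within set 2, 9 were lower and 1 higher, or 14 and 2 adjusted over the list alone (adjusted p = 0.866 with an estimated correlation), in a reference that includes the library pair without bFGF.

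Some stem cell and epithelial genes were lower without GSK3 inhibitors. Dppa5a (-5.32, SE 0.47, adjusted p = 0.000974), Sall4 (-3.33, SE 0.33), Cdh1 (-2.85, SE 0.43), Dsg2 (-4.66, SE 0.52) and the transferrin receptor gene Tfrc (-3.98, SE 0.36) were lower than in OSK. Within set 2 the values were -2.53, -1.94, -2.01, -3.35 and -3.22. Epithelial genes had 11 of 24 lower, with 11 also adjusted over the list alone, and late pluripotency genes 9 of 19 lower, or 9 lower and 1 higher (adjusted p = 0.576 with an estimated correlation for both). Within set 2 5 epithelial genes were lower, or 8 adjusted over the list alone (adjusted p = 0.889 with an estimated correlation), and 1 late pluripotency gene was lower, with 1 also adjusted over the list alone (adjusted p = 0.997 with an estimated correlation). Fibroblast genes had 14 of 32 higher and 1 lower, or 18 and 2 adjusted over the list alone (adjusted p = 0.576 with an estimated correlation), with Loxl1 at 2.60. Within set 2 they were 4 higher and 2 lower, or 4 and 4 adjusted over the list alone (adjusted p = 0.997 with an estimated correlation), with Loxl1 at 1.04. The mineralization inhibitor gene Mgp was 4.19 higher than in OSK (SE 0.39) and 1.88 higher within set 2 (SE 0.28). In all, 1415 genes were higher and 1894 lower. The GC trend removed left 1233, and 1384 differed from the other 2 omissions, 825 without bFGF omission day 3 and 122 without its day 7. Those without vitamin C omission day 3 were 896. Dsg2 was 1 of 6 named genes whose calls within set 2 ended without bFGF omission day 7.

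Without bFGF, some fibroblast genes were higher in both comparisons, and some stem cell genes were lower than in OSK. The collagen genes Col14a1 (4.10, SE 0.33, adjusted p = 0.000494) and Col1a1 (1.86, SE 0.23) and Mmp13 (3.40, SE 0.30) were higher than in OSK, and within set 2 they were 2.84 (SE 0.24), 1.63 (SE 0.19) and 3.50 (SE 0.23) higher. Nanog (-3.04, SE 0.52, adjusted p = 0.00998), Epcam (-2.17, SE 0.38) and Sall4 (-1.99, SE 0.30) were lower than in OSK. None of these 3 passed within set 2, where their values were -1.27 (SE 0.46), -0.95 (SE 0.34) and 0.06 (SE 0.26), and Dppa5a was at 0.98 there (SE 0.34, not passing). The other 2 omissions were themselves lower than OSK on day 7. Without vitamin C and without GSK3 inhibitors Nanog stood at 36.4 and 17.8 CPM against 98.5 CPM in OSK. Epcam stood at 189 and 29.2 against 204 CPM, and Sall4 at 78.8 and 14.5 against 138 CPM. The smaller values within set 2 therefore do not show that the differences from OSK came from the sets. Fibroblast genes had 17 of 32 higher, or 23 higher and 1 lower adjusted over the list alone, late pluripotency genes 11 of 19 lower, or 12, and epithelial genes 11 of 24 lower, or 14 (adjusted p = 0.508 with an estimated correlation for each of the 3). Within set 2 the fibroblast list had 5 higher and 1 lower, or 16 and 2 adjusted over the list alone, the epithelial list 2 lower, or 4, and the late list 0, or 2 lower (adjusted p = 0.643 with an estimated correlation for each).

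Of 19 Wnt/beta-catenin targets, 2 were higher without bFGF than in OSK and 1 lower, or 4 and 2 adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). Within set 2, 8 were higher without bFGF, or 13 adjusted over the list alone (adjusted p = 0.643 with an estimated correlation), including Axin2 (2.42, SE 0.30, adjusted p = 0.00506), Tcf7 (1.99, SE 0.22) and Sp5 (2.81, SE 0.54), in a reference that includes the library pair without GSK3 inhibitors. On day 7 Axin2 was at 134 CPM without bFGF, 63.5 CPM without vitamin C and 48.4 CPM in OSK, and the list without bFGF had a median ratio to OSK of 0.90 (percentile 99.99, with 9 of 18 at least 2-fold higher and 2 lower). The immediate early gene Egr1 was 2.44 higher than in OSK (SE 0.55, adjusted p = 0.0313), with 1.93 (SE 0.44, adjusted p = 0.0889) within set 2, and 4 of 20 FGF/ERK targets were higher, with 4 also adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). Within set 2 no FGF/ERK target passed, and 1 was higher and 1 lower adjusted over the list alone (adjusted p = 0.777 with an estimated correlation). In all, 668 genes were higher and 1103 lower than in OSK, 469 passed with the GC trend removed, 38 in 1 model over all 20 libraries, and 310 differed from the other 2 omissions. Within set 2, 108 passed without GSK3 inhibitor omission day 7, and the call of Lgr5, a Wnt target (3.54, SE 0.67, adjusted p = 0.046), ended without any single library of the other 2 omissions.

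Without vitamin C few genes differed from OSK, 6 higher and 36 lower. Among these were the interferon-inducible genes Tgtp2 (-3.03, SE 0.49, adjusted p = 0.0432), Ifit3 (-1.45, SE 0.24) and Usp18 (-1.20, SE 0.19), Dppa5a (-2.60, SE 0.40) and, higher, the long noncoding RNA gene Neat1 (1.49, SE 0.24). Interferon response genes had 2 of 20 lower, or 12 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Within set 2, 8 were lower, or 11 adjusted over the list alone (adjusted p = 0.662 with an estimated correlation), with Ifit3 at -1.79 (SE 0.22), Usp18 at -0.99 (SE 0.17) and Tgtp2 at -0.75 (SE 0.44, not passing). Dppa5a turned direction, to 1.55 (SE 0.34), and Neat1 at 0.46 (SE 0.20) did not pass. The 42 calls against OSK became 3 without either library of the bFGF omission, 18 without GSK3 inhibitor omission day 7, 6 with the GC trend removed and 316 with DESeq2. The calls of Neat1 and Dppa5a ended without any of those 3 libraries, and that of Tgtp2 without either library of the bFGF omission.

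Compared with the other 2 omissions, cells without vitamin C had more transcripts of some epithelial and a few stem cell genes. Esrp1 (4.92, SE 0.51, adjusted p = 0.0017), Grhl2 (3.39), Dsg2 (3.37, SE 0.37), Epcam (2.11, SE 0.31) and the proliferation gene Mki67 (1.60, SE 0.19) were higher, and Mgp (-3.09, SE 0.35), the complement gene Cfb (-3.41, SE 0.30) and H19 (-2.25, SE 0.24) were lower. Epithelial genes had 14 of 24 higher, or 18 adjusted over the list alone, and fibroblast genes 12 of 32 lower, or 16 lower and 1 higher (adjusted p = 0.662 with an estimated correlation for both). Late pluripotency genes had 5 of 19 higher, with 5 also adjusted over the list alone (adjusted p = 0.748 with an estimated correlation). With the GC trend removed 11 epithelial and 3 late pluripotency genes were higher. On day 7 the epithelial list lay at 4.58 without vitamin C, 4.38 in OSK, 2.84 without bFGF and 2.57 without GSK3 inhibitors, and the late pluripotency list at 3.43, 4.45, 2.73 and 2.83. In all, 1369 genes were higher and 481 lower, 650 passed without bFGF omission day 3 and 840 without GSK3 inhibitor omission day 7, and 510 with the GC trend removed. These 510 were 248 higher and 262 lower, and on series scores 214 were higher and 227 lower, so the excess of higher genes was not found with either.

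**Figure D3:**
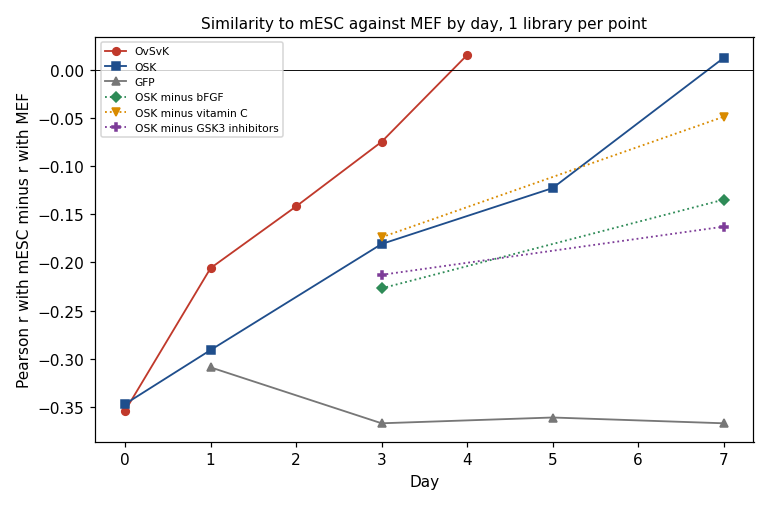
Pearson r with mESC minus r with MEF across 12897 genes of the log2 series score, against day, 1 library per point, with a line per arm. OvSvK rose from -0.354 on day 0 to 0.015 on day 4 and OSK from -0.347 to 0.012 on day 7, while GFP lay between -0.309 and -0.367.

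The profiles as a whole moved from MEF toward mESC in both factor arms. Across 12897 genes of the series score, r with mESC minus r with MEF was -0.075 on day 3 of OvSvK and -0.181 on day 3 of OSK, and 0.015 and 0.012 on their last days. The correlations themselves on the last days were 0.717 with mESC and 0.702 with MEF for OvSvK, and 0.669 and 0.658 for OSK. Without vitamin C the difference on day 7 was -0.049, without bFGF -0.135 and without GSK3 inhibitors -0.163. Genes are not independent replicates, and these values carry no test. Across genes, the difference of an omission from OSK on day 3 and that on day 7 correlated with r = 0.55 without bFGF, 0.31 without vitamin C and 0.61 without GSK3 inhibitors, and with r = 0.61, 0.72 and 0.72 against the other 2 omissions.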

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

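The tests of the patterns in Wnt targets, interferon response genes and Xist were chosen only after the results were seen, as was the comparison of each omission with the other 2 omissions, while the regroupings of libraries were fixed beforehand.

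OSK and GFP differed in how genes changed per day, in 862 genes. Each omission differed from the other 2 omissions within set 2, in 310 genes without bFGF, 1850 without vitamin C and 1384 without GSK3 inhibitors. Members of some lists passed in opposite directions between omissions, while none of these lists passed with an estimated correlation (adjusted p = 0.643 to 0.889). Fibroblast genes had 5 members higher without bFGF and 12 lower without vitamin C, and epithelial genes had 14 higher without vitamin C and 5 lower without GSK3 inhibitors. Wnt/beta-catenin targets had 8 higher without bFGF and 9 lower without GSK3 inhibitors, and interferon response genes had 10 higher without GSK3 inhibitors and 8 lower without vitamin C. These contrasts share libraries, so a change in 1 omission also moves the other contrasts the opposite way.

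Of 35 regroupings of the 8 OSK and GFP libraries, 3 gave no model fit, and only 1 of the other 32, the real grouping, gave as many as 3895 genes, with 0 in the next. Only 8 regroupings keep 1 library per day on each side, as the model with day as a block assumes, and 8 are too few for a share under 0.05. For OvSvK against OSK the 10 regroupings are too few for a share under 0.05. The real grouping gave 0 genes, as few as any, and the highest of the others gave 3, so that 10 of 10 gave as many. For the slopes of OSK and GFP, 9 of 100 regroupings gave as many as the real 862, the highest other giving 2262, and chance cannot be excluded. For the slopes of OvSvK and OSK the real count was 0, so that 100 of 100 gave as many by construction, which decides nothing, and the highest other gave 2285. Counts as high as 2262 and 2285 in other regroupings point to some structure of the samples, which was not tested.

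Of 19 Wnt/beta-catenin targets 11 were lower and 2 higher than in OSK without GSK3 inhibitors, and 9 lower and 1 higher within set 2, while the list did not pass with an estimated correlation (adjusted p = 0.576 and 0.866). For the lower values, the library sets are not the whole reason, since the list was also lower among libraries of set 2 (median -2.09, log2). The size of that median rests in part on the bFGF omission in its reference, where the list was above OSK on day 7 (4.29 against 3.54). Against the vitamin C omission alone, of the same set, the list's mean level was 2.15 against 2.36 on day 3 and 2.41 against 3.5 on day 7. A GC trend is not the whole reason either, since the median against both omissions was -1.94 with that trend removed. Slower reprogramming remains open: the list's mean level of 2.41 on day 7 lay within the 2.05 to 2.65 of OSK days 1 to 3. That level was below the 2.47 to 2.77 of GFP, the arm without the factors. Other lists placed this day 7 library later than OSK days 1 to 3. Its early and late pluripotency lists lay at 3.9 and 2.83, against 3.91 and 2.58 on OSK day 5. The Wnt list lay at 2.83 on OSK day 5. Its epithelial list, at 2.57, lay between OSK day 3 (2.46) and day 5 (3.22). On day 3 without GSK3 inhibitors the Wnt list lay at 2.15, against 2.65 in OSK. The early and late pluripotency lists then lay at 3.09 and 2.15, against 3.14 and 2.17 in OSK. The epithelial list lay at 2.1 against 2.46, so the lists of day 3 go both ways. Cells without bFGF, which were somewhat nearer to mESC on day 7, had the Wnt list at 4.29. Their r with mESC was 0.614, against 0.578 without GSK3 inhibitors. Axin2 at 6.16 CPM lay between its 2.43 CPM on day 0 and 13.7 CPM on day 1 of OSK, and GFP held 41.6 to 72.2 CPM. A candidate explanation that the design names is the missing inhibition of GSK3 itself, which these libraries do not separate from slower reprogramming.

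Of 20 interferon response genes 12 rose over the days of OvSvK, while the list did not pass with an estimated correlation (adjusted p = 0.131). A GC trend is not the whole reason, since 15 of the 20 members passed with that trend removed, and RNA of macrophages is not, since the median slope of the macrophage list was -0.7. A response shared with GFP transfection may contribute, as the list's median was 1.54 higher on day 3 than on day 1 of GFP (1.7 with the GC trend removed), with 18 of 20 members higher. Those 2 GFP libraries have no replicate, and no other biological explanation was tested.

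Xist, the RNA of the inactive X chromosome, stood at 163 CPM on day 0 and 778 to 865 CPM on later days of OvSvK, against 3.72 to 236 CPM in the other libraries. The library set is not the whole reason, since OvSvK day 3 lay 6.25-fold above the highest omission of day 3 in the same set, nor is a GC trend, since the ratio to OSK on day 3 was 3.43 (log2) with that trend removed. A larger share of female cells in OvSvK could not be decided. Of 8 comparisons of 4 Y-linked genes with OSK on days 1 and 3, 5 were lower in OvSvK, and 8 of 8 with the GC trend removed. On day 0, which was not counted, all 4 were higher in OvSvK. Ddx3y stood at 9.05 against 5.73 CPM, Uty at 3.99 against 1.5, Kdm5d at 5.32 against 3.94 and Eif2s3y at 5.72 against 4.8. OSK day 0 is the library that stood apart in GC, and these genes were not compared on day 0 with that trend removed. No other biological explanation was tested.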

How the results depend on the processing

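Alternatives chosen after seeing the data were removal of the GC trend, limma-trend on series scores, protein-coding genes only, leaving out OSK day 0 with GFP day 1, and contrasts among the omissions. No paired analysis was possible because the labels carry no replicate numbers, apart from day, which already served as a block in the tests of matched days. No gene named in a tested contrast reversed, except as given for contrasts among the omissions. With DESeq2 211 named results kept their side of the threshold and 5 did not, with RLE size factors 212 and 4, without a low-count filter 206 and 10, on log2(TPM + 1) 168 and 48, on series scores 176 and 39, and with the GC trend removed 193 and 23. On TPM the median of all genes moved from 0.05 to 0.203 for OSK against GFP, and to 0.184 for OvSvK against OSK, 0.112 for the OvSvK slope, 0.111 for vitamin C and -0.113 for bFGF within set 2, so directions on TPM are relative to these. In 1 model over all 20 libraries 38 kept it and 38 did not, with sampling points 79 and 1, and without OSK day 0 and GFP day 1 40 and 40. Depth limits what can be said of genes with about 3 counts or fewer in a library. The cause of each change below was not tested, except that leaving out libraries leaves fewer of them.

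Genes called without a low-count filter were 1011 for OvSvK against OSK, 139 without vitamin C and 471 without bFGF within set 2. With DESeq2 they were 1787 for OvSvK against OSK, 1796 for the OSK slope against the GFP slope, 405 for the OvSvK slope against the OSK slope, 2383 for the OvSvK slope, 2224 for the GFP slope, 316 without vitamin C and 609 without bFGF within set 2. With RLE size factors 10 passed for the OvSvK slope against the OSK slope. With limma-trend on log2(TPM + 1), 56 passed for that contrast, 1022 without bFGF, 7 without vitamin C, and within set 2 108 without bFGF and 638 without GSK3 inhibitors. With the GC trend removed they were 233 for OvSvK against OSK (1187 also without day 0), 1343 for the OSK slope against the GFP slope, 3 for the OvSvK slope against the OSK slope, 2200 for the OvSvK slope, 1022 for the GFP slope, 469 without bFGF, 6 without vitamin C, 1233 without GSK3 inhibitors, and within set 2 510 without vitamin C and 662 without GSK3 inhibitors. Single days then gave 2046 for OvSvK with OSK on day 0, and on day 3 840 without bFGF and 1047 without GSK3 inhibitors. With limma-trend on series scores 1 passed for OvSvK against OSK, 1788 for the OSK slope against the GFP slope, 47 for the OvSvK slope against the OSK slope, 2561 for the OvSvK slope, 1203 for the GFP slope, 305 without bFGF, 3 without vitamin C, 1127 without GSK3 inhibitors, and 73, 441 and 417 in that order within set 2. With protein-coding genes only, 1 passed for OvSvK against OSK and 8 for the OvSvK slope against the OSK slope.

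In 1 model over all 20 libraries 5856 passed for OSK against GFP, 3483 for OvSvK against OSK, 38 without bFGF, 1 without vitamin C and 204 without GSK3 inhibitors. With sampling points in place of days 79 passed for the OvSvK slope against the OSK slope and 1093 for the GFP slope. Without OSK day 0 and GFP day 1 these were 18 for the OSK slope against the GFP slope, 15 for the OvSvK slope against the OSK slope, 3498 for the OSK slope, 3163 for the OvSvK slope and 2 for the GFP slope. Against the other 2 omissions 310 differed without bFGF, 1850 without vitamin C and 1384 without GSK3 inhibitors. There the directions turned for 1700019G06Rik (-1.03), Rpsa-ps10 (0.938), Dppa5a (0.976) and Sall4 (0.06, not passing) without bFGF, and Rpsa-ps10 (0.213) and Dppa5a (1.551) without vitamin C, where Rpsa-ps10 separates the library sets. The value of AC136976.1 without GSK3 inhibitors (0.18) compares 0 counts with 0 counts and has no direction. The correlations of days 3 and 7 were 0.61, 0.72 and 0.72. With a floor of 20 CPM single days gave 1434 and 2163 for OSK with GFP on days 1 and 3, 1571 for OvSvK with OSK on day 3, 1449 for the last days, 1037 and 1335 without bFGF, 249 and 668 without vitamin C on days 3 and 7, and 1142 without GSK3 inhibitors on day 3, with correlations of 0.57, 0.31 and 0.65. With a floor of 1 CPM they were 967 and 1757 without vitamin C, with correlations of 0.5, 0.31 and 0.56. On series scores OvSvK with OSK on day 0 gave 2212.

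Leaving out 1 day or library gave 933 to 6012 for OSK against GFP, 17 to 1748 for OvSvK against OSK, 0 to 1074 for the OSK slope against the GFP slope, 0 to 14 for the OvSvK slope against the OSK slope, 2908 to 6845 for the OSK slope, 189 to 2651 for the OvSvK slope and 0 to 2646 for the GFP slope. For bFGF, vitamin C and GSK3 inhibitors, leaving out 1 library of the other 2 omissions gave 1319 to 1660, 3 to 50 and 2377 to 2935 against OSK, and 108 to 303, 650 to 1768 and 122 to 998 within set 2. Libraries of OSK and of the omission itself were not left out, so these ranges do not show how far the counts rest on them.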

Other observations

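The tests of lists here were fixed before the data were examined, and Myh2 and Hbb-y were singled out after their values were seen.

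Transcripts of genes from other lineages appeared in the factor arms. The embryonic globin gene Hbb-y (ENSMUSG00000052187) stood at 44.5 to 199 CPM in OSK, 13.4 to 76.3 CPM in OvSvK, lowest on day 4, and 0 to 0.251 CPM as measured in GFP, and reached 310 and 325 CPM on day 3 without bFGF and without GSK3 inhibitors. Of the erythroid list 2 members were measured, Hbb-y and 1 other, too few for a test. Their mean log2(CPM + 1) was 3.03 to 4 in OSK, 1.93 to 3.23 in OvSvK and 0 to 0.25 in GFP. That mean rests mainly on Hbb-y and is no separate evidence for the list. The adult alpha-globin gene Hba-a1 had 0 counts in OSK days 1 to 7 and in GFP. The muscle myosin gene Myh2 (ENSMUSG00000033196) stood at 7.59 to 308 CPM in the factor arms and at 0 counts in all 4 GFP libraries. The myogenic list as a whole had 3 of 7 members rising and 1 falling per day in OvSvK, or 3 and 2 adjusted over the list alone (adjusted p = 0.604 with an estimated correlation).

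Neural genes were higher in OSK than in GFP in 4 of 6 tested members, with 4 also adjusted over the list alone (adjusted p = 0.59 with an estimated correlation), among them Sox11 (2.28), Tubb3 (2.18) and Nes (2.28). Trophoblast genes had 3 of 5 higher, with 3 also adjusted over the list alone (adjusted p = 0.73 with an estimated correlation). Endoderm genes had 1 of 4 lower, or 2 adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). The endothelial list had 1 of 4 higher and 1 lower, with the same counts adjusted over the list alone, and its median of -0.25 and mean of 0.81 differed in sign (adjusted p = 0.59 with an estimated correlation). Macrophage genes had 1 of 4 higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Primitive streak and mesoderm genes had 2 of 4 rising per day in OvSvK, with 2 also adjusted over the list alone (adjusted p = 0.0746 with an estimated correlation), and their level reached 2.49 on day 4 of OvSvK and 1.3 on day 7 of OSK. Of 3 tested germline genes methylated in fibroblasts, 1 was lower without bFGF, or 2 adjusted over the list alone (adjusted p = 0.518 with an estimated correlation).

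Metabolic and stress lists were also compared between OSK and GFP. Cholesterol synthesis genes had 1 of 17 higher and 5 lower, or 1 and 6 adjusted over the list alone (adjusted p = 0.673 with an estimated correlation). Glycolysis genes had 3 of 16 higher, with 3 also adjusted over the list alone (adjusted p = 0.835 with an estimated correlation), and hypoxia targets 3 of 16 higher and 4 lower, with the same counts adjusted over the list alone (adjusted p = 0.835 with an estimated correlation). Stress response genes had 2 of 13 higher and 3 lower, or 2 and 4 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation), with the heat shock gene Hspa1b at -2.65 and Hmox1 at -1.61. The reprogramming factor list, which holds Myc beside the 3 introduced factors, had 4 of 4 higher, with 4 also adjusted over the list alone (adjusted p = 0.124 with an estimated correlation).

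In GFP, 22 of 24 cell cycle genes were lower on day 7 than on day 3, with a median log2 difference of -1.08. Between mESC and MEF, on the series scores alone, 3322 genes were at least 2-fold higher and 3457 lower in mESC, with no test.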
